A study of Mus musculus with 20 samples.

How the data were processed

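Total RNA of mouse liver cells was measured by RNA sequencing in 20 libraries of 5 groups, and per the labels' protocols it was isolated with the RNeasy Micro kit and made into libraries with the KAPA Stranded mRNA-Seq kit. Per the submitters' processing notes, FastQC, Trimmomatic, STAR 2.5.3a and RSEM 1.2.28 were used with the mm10 build, without the role, the order or the settings of each being stated. The deposited values are 1 table of 24848 genes by symbol per library. The deposited expected count of each gene is the RSEM estimate, not normalised, per the file headers and the values, of which 0.64% to 0.87% of genes per library carried a decimal fraction as printed. The deposited TPM values are RSEM's transcripts scaled to a common total per library, per the file headers. The deposited FPKM values, also from RSEM per the file headers, entered no test.

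Libraries were grouped by their titles. The titles place the cultured stellate cells at 7 days and the series description at 3 days, and the titles were followed. The comparisons were fresh PMSC against fresh HSC, PMSC-MF-3d against PMSC, PMSC-MF-7d against PMSC-MF-3d, PMSC-MF-7d against PMSC, HSC-MF-7d against HSC and PMSC-MF-7d against HSC-MF-7d. The seventh was the difference between the culture changes of PMSC and HSC. The groups, the design, the gene lists, the rule for the named genes and most alternatives were fixed before the data were examined.

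Expected counts were rounded and tested with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were left out by filterByExpr, which kept 14751 genes and left out 10097. Library sizes were scaled by trimmed means of M-values (TMM). A robust quasi-likelihood model with a mean for each of the 5 groups was fitted to all 20 libraries, so that the groups share an estimate of the spread. P-values were adjusted over all tested genes by the method of Benjamini and Hochberg, and an adjusted p under 0.05 was called. The standard error of a log2 fold change was taken as its size over the square root of the F statistic. CPM values use the TMM-scaled library sizes, and the principal components use log2 CPM with a prior count of 2. Tested genes were matched on symbol and accession to a table of the GRCm38.p6 assembly, the assembly behind mm10, for 14434 genes or 97.9%.

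Of 42 gene lists written down, 40 were tested as groups with camera of limma 3.58.1, at a preset correlation of 0.01 between genes and again with the correlation estimated for each list, and with fry. Camera compares a list with all other genes, and fry asks only whether its members move one way on balance. The p-values of the lists were adjusted over the lists of a comparison. A list is described as higher or lower only with its counts of members past the edgeR threshold. Most calls at the preset correlation were not kept with an estimated correlation. Camera called 20, 24, 8, 20, 20, 11 and 21 lists in the 7 comparisons in the order above, and 3, 8, 1, 5, 9, 1 and 4 lists with an estimated correlation.

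The genes named were set by a rule with 3 parts. The rule's opening part took, per comparison of groups, the 6 largest and the 6 smallest log2 fold changes among called genes. These genes had at least 20 CPM in the higher group and no overlap between the groups' libraries, which chance gives for 2.86% of genes. Predicted genes and small RNA genes were left out of that part. It was followed by a panel of 26 marker genes and, for each list described, up to 4 called members with the largest changes and at least 10 CPM in the higher group. The opening part is not defined for the difference of the culture changes. The rule gives more genes than were printed, and which panel genes and list members were printed was chosen after their values were seen. Genes needed for a check, such as sex-linked genes and abundant genes of other cell types, were also named.

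A fold change against a group with no counts is given as a lower bound at 3 counts over the group's 4 libraries. This floor was 0.0520 CPM in PMSC, 0.0281 in PMSC-MF-3d, 0.0278 in PMSC-MF-7d, 0.0449 in HSC and 0.0415 in HSC-MF-7d. With 1 to 3 counts the ratio is given with its 95% counting interval. Intervals and floors cover counting error only. Genes of families with near-identical members are uncertain, since RSEM divides the reads they share. Among those named are Prl2c2 and Prl2c3, Lce1g and Lce1h, Saa1 and Saa2, Serpina1b, Psg22, Fcgr4, Gbp5 and the H2 genes.

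The test was tried on simulated data with known changes in 67, 67 and 66 of 14751 genes at 1.5-fold, 2-fold and 4-fold. For PMSC against HSC it recovered 35.8%, 53.7% and 89.4% of them, with 8.9% false among the calls. For PMSC-MF-3d against PMSC it recovered 49.3%, 74.6% and 95.5%, with 5.08% false. For PMSC-MF-7d against PMSC-MF-3d it recovered 52.2%, 80.6% and 97.0%, with 7.65% false, and for PMSC-MF-7d against PMSC 40.3%, 70.1% and 93.9%, with 6.88% false. For HSC-MF-7d against HSC it recovered 38.8%, 67.2% and 95.5%, with 9.09% false, and for PMSC-MF-7d against HSC-MF-7d 55.2%, 80.6% and 93.9%, with 3.98% false. Small fold changes were thus often missed in these simulated data. The share of false calls exceeded the nominal 5% in 5 of the 6 comparisons. Far fewer genes changed there than were called in the real data, which makes the adjusted threshold stricter. The shares recovered therefore do not carry over to the real comparisons.

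The alternatives were DESeq2 1.42.0, its size factors in edgeR, library totals without TMM, no filter, a filter of 10 CPM in 4 libraries, a fit of only the compared groups, the replicate number as a block and a threshold on the fold change of 1.5. Limma on log2(TPM + 1) and leaving out each library in turn were also run. Camera was also run with the replicate block, at the preset and at an estimated correlation. The 4 alternatives added after the data were seen are named in the closing section. Samples with the same replicate number were not treated as paired. Gene length and GC content were not examined.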

Results

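RNA was sequenced from mesenchymal cells of the C57BL/6 mouse liver. Portal mesenchymal stem cells (PMSCs) are stromal cells from around the portal vein, and hepatic stellate cells (HSCs) are the vitamin A-storing pericytes of the sinusoids. Both were profiled without culture, here called fresh, and as the myofibroblasts they gave rise to in culture. Myofibroblasts are the contractile, matrix-producing cells of scar tissue. The portal cells were cultured for 3 days (PMSC-MF-3d) or 7 days (PMSC-MF-7d). The stellate cells were cultured for 7 days by the sample titles (HSC-MF-7d), which were followed, but for 3 days by the series description. The time of this group is therefore uncertain. Each of the 5 groups held 4 libraries, 20 in all. Summed expected counts per library ranged from 11810532 to 21438753 in PMSC, 23641579 to 24258856 in PMSC-MF-3d and 22738017 to 26675589 in PMSC-MF-7d. They ranged from 14806349 to 18650355 in HSC and 13572278 to 18382038 in HSC-MF-7d. Levels are given in CPM, normalised counts scaled to a common library size, as mean ± SD over the 4 libraries of a group. Log2 fold changes are given with their standard error (± SE). No label says whether the libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples. That spread may be technical. How the cells were isolated or sorted is not given in the sources used here. All 20 libraries carried the Y-linked transcript Ddx3y, with group means from 89.7 to 438 CPM, and Xist stayed at or under 2.15 CPM in each.

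The groups separated in a principal component analysis of log2 CPM. The first component held 55.8% of the variance and parted the fresh from the cultured libraries. The second held 26.1% and parted fresh PMSC from fresh HSC. The spread between replicates, as the biological coefficient of variation, was 28.7% in PMSC, 10.7% in PMSC-MF-3d and 19.6% in PMSC-MF-7d. It was 27.6% in HSC and 7.81% in HSC-MF-7d. The tests shared an estimate of the spread over all groups despite this. Fits of only the compared groups, with their own filter and scaling, called 9159 genes in place of 10872 for PMSC against HSC. For PMSC-MF-7d against HSC-MF-7d they called 7873 in place of 6941. On the mm10 build, Cd34 lies on chromosome 1 from 194938821 to 194961292, and Slit2 on chromosome 5 from 47981291 to 48307735. Reln lies on chromosome 5 from 21884454 to 22344705 and Gli1 on chromosome 10 from 127329882 to 127341579. Lrat lies on chromosome 3 from 82892582 to 82903974 and Acta2 on chromosome 19 from 34240336 to 34255585. Col1a1 lies on chromosome 11 from 94936224 to 94953042 and Mki67 on chromosome 7 from 135689784 to 135716450. These spans are the whole genes, exons and introns together, and each value is the count over all annotated transcripts of the gene.

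**Figure D1:**
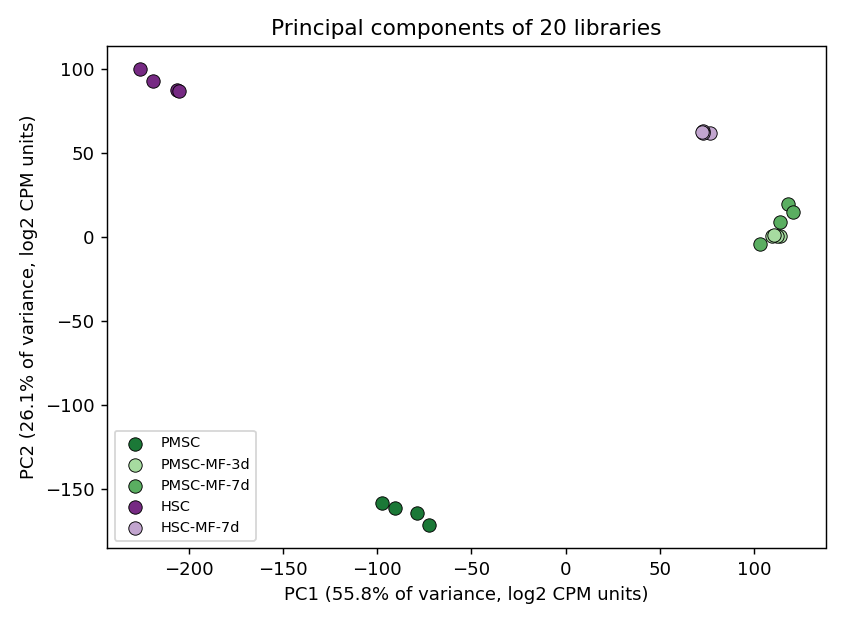
Principal components of log2 CPM, with 1 point per library colored by group; the axes give the share of variance of each component in log2 CPM units. The fresh HSC libraries sit below -205 on the first component and every cultured library above 72.

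The comparison of fresh PMSCs with fresh HSCs asked how the source populations differ. Cd34, a surface sialomucin of progenitor and endothelial cells, averaged 1267 ± 206 CPM in PMSCs and 8.35 ± 0.69 in HSCs, a log2 fold change of 7.24 ± 0.35 (edgeR adjusted p = 6.4e-13). Gli1, a transcription factor of the hedgehog pathway, was higher in PMSCs by 7.86 ± 0.55 on the log2 scale and elastin (Eln) by 6.05 ± 0.77 (adjusted p at or below 8.2e-07). Reelin (Reln), a secreted glycoprotein, averaged 6548 ± 1390.0 CPM in HSCs and 47.3 ± 20.97 in PMSCs (log2 fold change -7.11 ± 0.35, adjusted p = 1.2e-12). Lrat, which esterifies retinol for storage, averaged 1568 ± 73.1 CPM in HSCs and 161 ± 81.97 in PMSCs (log2 fold change -3.28 ± 0.32, adjusted p = 1.6e-08). Of 14751 genes tested, 4959 were higher in PMSCs and 5913 lower, and of a panel of 26 marker genes 17 were higher and 7 lower. Counts of list members given below were the same adjusted over the list alone unless stated. Over all comparisons 31 list calls held with an estimated correlation, and all 31 held with the replicate number added as a block at the preset correlation. With the block and an estimated correlation together, 7 of the 31 held.

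Several of the genes furthest up in PMSCs had no count in any HSC library. The calcium channel gene Cacna1g was at least 2817-fold higher, the protease gene Adamts8 at least 1607-fold, the matricellular gene Wisp2 at least 1468-fold and the angiopoietin gene Angpt4 at least 1448-fold. Has1, a hyaluronan synthase, averaged 967 ± 609 CPM in PMSCs against 0.060 ± 0.12. Slit2, a secreted axon guidance ligand, had 1 count over the 4 HSC libraries and was 7546-fold (95% counting interval 1354 to 298100.0) higher in PMSCs. The 6 genes furthest down had no count in any PMSC library. These were the macrophage receptor genes Cd163 (at least 7434-fold lower), Vsig4 (at least 6339-fold) and Marco (at least 4124-fold), together with Wfdc17 (at least 1978-fold), Cd300ld (at least 1710.0-fold) and Fcgr4 (at least 1252-fold).

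Of the portal fibroblast markers, 26 of 27 were higher in PMSCs and 1 lower (camera adjusted p = 9.3e-14, adjusted p = 0.051 with an estimated correlation). Mfap4, a microfibril protein, differed by 12.78 ± 0.53, Clec3b, encoding tetranectin, by 11.29 ± 0.46, and Fbln1, encoding fibulin, by 11.21 ± 0.20 (adjusted p at or below 9.7e-14). Of the stellate cell markers, 22 of 28 were lower in PMSCs and 3 higher (camera adjusted p = 6.5e-09, adjusted p = 0.059 with an estimated correlation; adjusted over the list alone 3 higher and 23 lower). The ficolin gene Fcna differed by -10.73 ± 0.41, the collectin gene Colec10 by -8.02 ± 0.35 and the hepatocyte growth factor gene Hgf by -3.60 ± 0.32. Fibrillar collagens and related matrix were higher for 21 of 24 members and lower for 1 (camera adjusted p = 2.3e-09, adjusted p = 0.088 with an estimated correlation). Col1a1 averaged 8413 ± 1382 CPM in PMSCs and 239 ± 186 in HSCs, and Col12a1 had a log2 fold change of 6.67 ± 0.50. Collagen processing genes were higher for 20 of 23 and lower for 2 (camera adjusted p = 1.1e-06, adjusted p = 0.088 with an estimated correlation), among them the crosslinking enzyme gene Lox (7.08 ± 0.39). Elastic fibre genes were higher for 16 of 18 and lower for 1 (camera adjusted p = 1.4e-09, adjusted p = 0.052 with an estimated correlation). Basement membrane genes were higher for 15 of 22 and lower for 4 (camera adjusted p = 1.0e-05). Col4a6 differed by 9.83 ± 0.31 and the laminin gene Lama1 by -8.11 ± 0.33. Matrix proteases and their inhibitors were higher for 16 of 22 and lower for 2 (camera adjusted p = 7.1e-07), with Mmp3 at 10.59 ± 0.55 and the inhibitor Timp1 at 6.03 ± 0.36.

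G2/M genes were lower in PMSCs for 27 of 30 members (camera adjusted p = 3.0e-06, adjusted p = 0.15 with an estimated correlation). Levels were low in both, with Mki67, a marker of cycling cells, at 8.13 ± 4.88 CPM in PMSCs and 27.9 ± 6.90 in HSCs. Immediate-early and stress genes were higher for 17 of 27 members and lower for 4 (camera adjusted p = 0.0018, adjusted p = 0.43 with an estimated correlation), with the AP-1 subunit gene Fosl1 at 7.76 ± 0.33. The interleukin gene Il6 averaged 1565 ± 471 CPM in PMSCs and 15.02 ± 8.25 in HSCs (adjusted p = 4.4e-12). Glycolysis genes were higher for 12 of 20 members and lower for 6 (camera adjusted p = 0.043, adjusted p = 0.21 with an estimated correlation), a direction that turned to 7 higher and 8 lower when libraries were scaled by their totals alone. Markers of other liver cell types went with the HSC libraries. Hepatocyte markers were lower in PMSCs for 22 of 23 members (camera adjusted p = 0.0049, adjusted p = 0.61 with an estimated correlation). Endothelial markers were lower for 19 of 20 (camera adjusted p = 1.1e-08, adjusted p = 0.088 with an estimated correlation) and macrophage markers for 19 of 19 (camera adjusted p = 2.0e-08, adjusted p = 0.17 with an estimated correlation). Albumin (Alb) ranged from 2534 to 10514 CPM over the 4 HSC libraries. The sinusoidal endothelial receptor gene Stab2 averaged 1425 ± 126 CPM and the Kupffer cell lectin gene Clec4f 1319.5 ± 761 CPM there. Fresh PMSCs carried less of these transcripts, with Alb at 65.4 ± 45.9 CPM and Stab2 at 13.01 ± 1.93 CPM. Antigen presentation genes were lower in PMSCs for 13 of 16 members (camera adjusted p = 0.0017, adjusted p = 0.21 with an estimated correlation). Among them were Cd74 (-4.66 ± 0.50) and H2-Aa (-4.66 ± 0.40), which macrophages and other antigen-presenting cells express.

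Scaling by library totals in place of trimmed means moved the median log2 fold change of all genes from -0.10 to -0.44 in this comparison and from -0.07 to 0.41 for PMSC-MF-3d against PMSC. It moved to 0.43 for PMSC-MF-7d against PMSC and from 0.10 to 0.44 for the difference of the culture changes. The changes given are relative to the trimmed-mean scale. The share of called genes that were higher in PMSCs was 45.6% with trimmed means, 33.3% with totals and 31.6% with limma on log2(TPM + 1). Without HSC replicate 2 the log2 fold change of Col12a1 was 8.16, and without HSC replicate 3 that of Gli1 was 9.39.

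**Figure D2:**
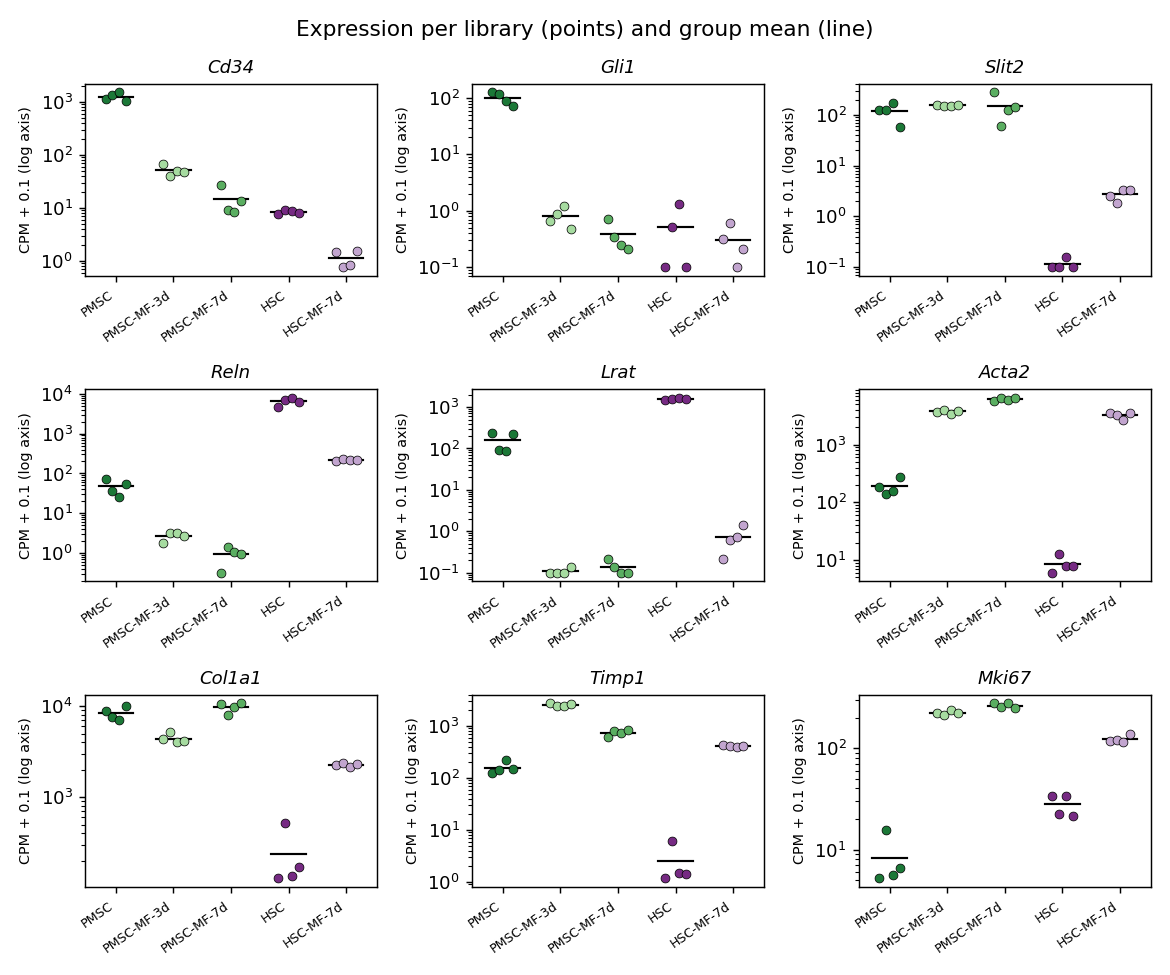
Expression of 9 genes in CPM + 0.1 on a log axis, with 1 point per library and a line at the mean of each group. Cd34, Gli1 and Slit2 sit highest in the portal cells, Reln and Lrat in fresh HSCs, and Acta2 and Mki67 in the cultured groups.

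The comparison of PMSC-MF-3d with fresh PMSCs covered the early part of the culture. Acta2, the smooth muscle actin of myofibroblasts, rose from 189.8 ± 60.2 to 3757 ± 256 CPM (log2 fold change 4.31 ± 0.21, edgeR adjusted p = 5.1e-13). Mki67 rose from 8.13 ± 4.88 to 222 ± 9.51 CPM (4.75 ± 0.26, adjusted p = 2.9e-12). Cd34 fell to 50.9 ± 10.8 CPM (-4.64 ± 0.30), Gli1 to 0.71 ± 0.31 CPM (-7.14 ± 0.50) and Il6 to 7.99 ± 0.72 CPM (-7.61 ± 0.38; adjusted p at or below 9.3e-11). In this comparison 5482 genes rose and 6064 fell, and of the 26 panel genes 7 rose and 17 fell.

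The genes furthest up were the prolactin family members Prl2c2 (at least 616-fold higher) and Prl2c3 (at least 417-fold), which share near-identical sequence, and the chromatin protein gene Hmga2 (10.52 ± 0.44). The cornified envelope gene Lce1g was 1416-fold (95% counting interval 254 to 55970.0) higher, and the cholecystokinin gene Cck (9.75 ± 0.46) and the tolloid protease gene Tll1 (9.45 ± 0.42) followed. Of those furthest down, Lrat was 18080.0-fold (95% counting interval 3245 to 714400.0) lower and the interferon-induced GTPase gene Gbp5 10820.0-fold (95% counting interval 1942 to 427500.0). The others were the cytochrome P450 gene Cyp2e1 (-13.000 ± 0.67), Serpina3c (at least 1168-fold lower), Adamts13 (at least 948-fold) and the chemokine gene Cxcl10 (-11.64 ± 0.48).

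Cell cycle genes rose nearly as a block. All 30 of 30 G2/M members rose (camera adjusted p = 4.4e-33; median log2 fold change 5.68), among them Ccnb1 (7.62 ± 0.37), Bub1 (8.61 ± 0.35) and Top2a (5.99 ± 0.30). In the G1/S list 28 of 30 members rose while 2 fell (camera adjusted p = 1.8e-20). Contractile genes rose for 19 of 22 and fell for 1 (camera adjusted p = 2.0e-09; adjusted over the list alone 19 higher and 2 lower), with Actg2 at 4.94 ± 0.26 and the calponin gene Cnn1 at 3.42 ± 0.24. Portal fibroblast markers fell for 23 of 27 and rose for 1 (camera adjusted p = 7.8e-06, adjusted p = 0.18 with an estimated correlation), with Clec3b at -11.31 ± 0.45 and the dermatopontin gene Dpt at -9.18 ± 0.48. Stellate markers fell for 27 of 28 (camera adjusted p = 2.9e-09, adjusted p = 0.067 with an estimated correlation).

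Matrix genes moved apart. Fibrillar collagens and related matrix fell for 16 of 24 members and rose for 4 (camera adjusted p = 0.0048, adjusted p = 0.41 with an estimated correlation), with decorin (Dcn) at -6.17 ± 0.28, Col3a1 at -3.32 ± 0.20 and Col1a1 at -0.93 ± 0.30 (adjusted p at or below 0.0091). Basement membrane genes fell for 17 of 22 (camera adjusted p = 0.0012) and elastic fibre genes fell for 12 of 18 and rose for 2 (camera adjusted p = 8.3e-04, adjusted p = 0.19 with an estimated correlation). Timp1 rose by 3.995 ± 0.31 and Lox by 2.02 ± 0.30, while Eln fell to 13.9 ± 4.93 CPM (-6.14 ± 0.77).

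Immune and stress genes fell. Immediate-early and stress genes fell for 25 of 27 (camera adjusted p = 6.4e-18), with Fosb at -9.70 ± 0.38 and Atf3 at -8.86 ± 0.36. Interferon response genes fell for 23 of 24 (camera adjusted p = 2.4e-13, adjusted p = 0.060 with an estimated correlation) and antigen presentation genes for 15 of 16 (camera adjusted p = 3.7e-12). Complement genes fell for 17 of 19 and rose for 1 (camera adjusted p = 5.4e-07), with C4b at -9.01 ± 0.68. Chemokines and cytokines fell for 25 of 28 and rose for 2 (camera adjusted p = 1.3e-04). Oxidative phosphorylation genes rose for 17 of 24 and fell for 1 (camera adjusted p = 0.0030, adjusted p = 0.41 with an estimated correlation). Glycolysis genes rose for 12 of 20 and fell for 6 (camera adjusted p = 0.036, adjusted p = 0.24 with an estimated correlation). Markers of other cell types, at low levels in fresh PMSCs, went down with these groups, and their source was not tested. Alb fell from 65.4 ± 45.9 to 0.32 ± 0.29 CPM and the endothelial gene Pecam1 from 17.4 ± 14.1 to 0.23 ± 0.11 CPM. Hepatocyte markers fell for 22 of 23 (camera adjusted p = 0.031, adjusted p = 0.65 with an estimated correlation) and endothelial markers for 19 of 20 (camera adjusted p = 0.0017, adjusted p = 0.41 with an estimated correlation). The share of called genes that rose was 47.5% with trimmed means, 61.7% with library totals and 60.0% with limma on log2(TPM + 1). The log2 fold change was 13.40 for Cck without PMSC replicate 1, 8.88 for Ccnb1 without PMSC replicate 2 and 11.81 for Hmga2 without PMSC replicate 4.

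PMSC-MF-7d were set against PMSC-MF-3d to follow the culture from day 3 to day 7. Acta2 went from 3757 ± 256 to 6059.6 ± 398 CPM (log2 fold change 0.69 ± 0.19, edgeR adjusted p = 0.0070) and Col1a1 from 4415 ± 548 to 9813 ± 1308 CPM (1.15 ± 0.31, adjusted p = 0.0060). Thy1, a surface glycoprotein of fibroblasts, rose by 2.82 ± 0.35, and the progenitor antigen gene Ly6a by 3.49 ± 0.37, while Cd34 fell by 1.82 on the log2 scale (adjusted p at or below 3.9e-05). Mki67 held 222 ± 9.51 and 262 ± 15.5 CPM and did not pass the test (adjusted p = 0.42). In all 2744 genes rose and 2566 fell, and of the 26 panel genes 7 rose, 7 fell and 12 did not pass.

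The genes furthest up were the fibrillar collagen gene Col2a1 (7.71 ± 0.88), Sorbs2 (5.92 ± 0.48), Wisp2 (5.09 ± 0.36), the retinoic acid-degrading enzyme gene Cyp26b1 (4.42 ± 0.57), Cd24a (4.21 ± 0.32) and Clca3a1 (3.99 ± 0.31). Those furthest down were Mmp3 (-5.72 ± 0.43), the proenkephalin gene Penk (-5.25 ± 0.38), the cytokine gene Il11 (-4.97 ± 0.36), the cholesterol transporter gene Star (-4.58 ± 0.31), Cilp (-4.27 ± 0.54) and Akr1c18 (-4.22 ± 0.61). All 12 had an adjusted p at or below 5.5e-05.

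Contractile genes rose for 13 of 22 members and fell for 3 (camera adjusted p = 1.2e-04, adjusted p = 0.37 with an estimated correlation), with Cnn1 at 2.58 ± 0.22 and the smooth muscle myosin gene Myh11 at 2.27 ± 0.27. Vascular smooth muscle and pericyte markers, of which Cnn1 and Myh11 are also members, rose for 8 of 14 and fell for 2 (camera adjusted p = 0.0042, adjusted p = 0.19 with an estimated correlation; adjusted over the list alone 9 higher and 2 lower). Fibrillar collagens and related matrix rose for 14 of 24 and fell for 2 (camera adjusted p = 3.7e-04, adjusted p = 0.70 with an estimated correlation; adjusted over the list alone 15 higher and 2 lower), with fibronectin (Fn1) at 2.23 ± 0.16, Col14a1 at 2.45 ± 0.25 and lumican (Lum) at -3.84 ± 0.52. Collagen processing genes rose for 13 of 23 (camera adjusted p = 0.0019, adjusted p = 0.58 with an estimated correlation). Basement membrane genes rose for 13 of 22 and fell for 4 (camera adjusted p = 2.6e-04, adjusted p = 0.081 with an estimated correlation; adjusted over the list alone 14 higher and 4 lower), with Col4a5 at 1.41 ± 0.088.

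G1/S genes fell for 17 of 30 members (camera adjusted p = 7.5e-07, adjusted p = 0.13 with an estimated correlation), with Mcm5 at -0.90 ± 0.13 and Cdc6 at -0.97 ± 0.19, whereas G2/M genes fell for 3 of 30 and the list was not called (camera adjusted p = 0.45); adjusted over the list alone no G2/M gene passed the edgeR test, with 7 at an unadjusted p under 0.05. Cell cycle inhibitors and p53 targets rose for 11 of 18 and fell for 1 (camera adjusted p = 2.6e-04), with the inhibitor genes Cdkn2a at 3.37 ± 0.43 and Cdkn2b at 2.52 ± 0.30 (adjusted p at or below 6.3e-06). Oxidative phosphorylation genes fell for 10 of 24 (camera adjusted p = 0.0064, adjusted p = 0.84 with an estimated correlation; adjusted over the list alone 11 lower). The TGF-beta ligand gene Tgfb1 fell by 2.08 ± 0.084 on the log2 scale (adjusted p = 2.5e-12), and Timp1 from 2542 ± 170.1 to 743 ± 91.1 CPM. The share of called genes that rose was 51.7% here, 45.1% with library totals, 47.9% with DESeq2 size factors and 64.4% with limma on log2(TPM + 1). The log2 fold change was -5.48 for Cilp and -5.32 for Lum without PMSC-MF-7d replicate 1, and 9.33 for Col2a1 without PMSC-MF-3d replicate 3.

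Over the whole culture, from fresh PMSCs to PMSC-MF-7d, Acta2 rose from 189.8 ± 60.2 to 6059.6 ± 398 CPM (log2 fold change 4.996 ± 0.22, edgeR adjusted p = 1.0e-13). Cd34 fell from 1267 ± 206 to 14.4 ± 8.61 CPM (-6.46 ± 0.33, adjusted p = 8.9e-13), Gli1 fell by 8.47 and the portal marker gene Dpt fell by 11.66 on the log2 scale (adjusted p at or below 3.9e-11). Col1a1 stood at 8413 ± 1382 and 9813 ± 1308 CPM (adjusted p = 0.51) and Slit2 at 120.1 ± 46.7 and 151 ± 91.5 CPM (adjusted p = 0.35), and neither passed the test. The test called 5613 genes higher and 5746 lower, and of the 26 panel genes 9 were higher and 15 lower.

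The genes furthest up were Prl2c2 (at least 718-fold higher), Hmga2 (11.43 ± 0.44), the lectin gene Siglecg (2189-fold (95% counting interval 606 to 18080.0)), the hyaluronan-binding protein gene Cemip (10.18 ± 0.42), Crct1 (1509-fold (95% counting interval 271 to 59630.0)) and Tll1 (9.84 ± 0.42). Among those furthest down were the complement gene C7 (-12.42 ± 0.41), the methyltransferase gene Inmt (-12.12 ± 0.30), the chemokine gene Ccl19 (-12.07 ± 0.47), Cyp2e1 (-11.98 ± 0.62) and Olfml1 (5157-fold (95% counting interval 1427 to 42590.0) lower).

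Contractile genes rose for 19 of 22 members (camera adjusted p = 2.9e-14), with Actg2 at 6.69 ± 0.28 and Cnn1 at 6.001 ± 0.26. All 30 of 30 G2/M genes rose (camera adjusted p = 6.5e-34), with Mki67 at 4.99 ± 0.27 and Ccnb1 at 7.49 ± 0.37, as did 28 of 30 G1/S genes (camera adjusted p = 1.9e-15). The inhibitor genes Cdkn2a and Cdkn2b rose too, by 5.003 ± 0.52 and 4.90 ± 0.36. Portal fibroblast markers fell for 22 of 27 and rose for 3 (camera adjusted p = 4.9e-06, adjusted p = 0.099 with an estimated correlation), Thy1 being among those that rose (1.97 ± 0.33). Elastic fibre genes fell for 11 of 18 and rose for 2 (camera adjusted p = 0.0019, adjusted p = 0.18 with an estimated correlation), with Fbln1 at -8.25 ± 0.17. Stellate markers fell for 27 of 28 (camera adjusted p = 8.7e-11, adjusted p = 0.065 with an estimated correlation), with Lrat at -11.86 ± 0.59.

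Immediate-early and stress genes fell for 26 of 27 members and rose for 1 (camera adjusted p = 3.1e-19, adjusted p = 0.055 with an estimated correlation), with Fosb at -10.35 ± 0.39. Interferon response genes fell for 23 of 24 (camera adjusted p = 3.1e-13, adjusted p = 0.055 with an estimated correlation) and antigen presentation genes for 15 of 16 (camera adjusted p = 4.2e-13). Complement genes fell for 18 of 19 and rose for 1 (camera adjusted p = 2.7e-07, adjusted p = 0.055 with an estimated correlation), and chemokines and cytokines fell for 25 of 28 and rose for 1 (camera adjusted p = 1.2e-06), with Il6 at -6.52 ± 0.36 and Ccl2 at -4.79 ± 0.42. Hepatocyte markers fell for 22 of 23 (camera adjusted p = 0.029, adjusted p = 0.64 with an estimated correlation) and endothelial markers for 18 of 20 (camera adjusted p = 9.6e-04, adjusted p = 0.44 with an estimated correlation). After 7 days Alb stood at 0.38 ± 0.61 CPM and Pecam1 at 0.16 ± 0.12 CPM. The share of called genes that rose was 49.4% with trimmed means, 63.5% with library totals and 65.2% with limma on log2(TPM + 1). The log2 fold change was 8.71 for Ccnb1 without PMSC replicate 2, 6.36 for Cdkn2a without PMSC replicate 1, 12.73 for Hmga2 without PMSC replicate 4 and -13.05 for Lrat without PMSC-MF-7d replicate 1.

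**Figure D3:**
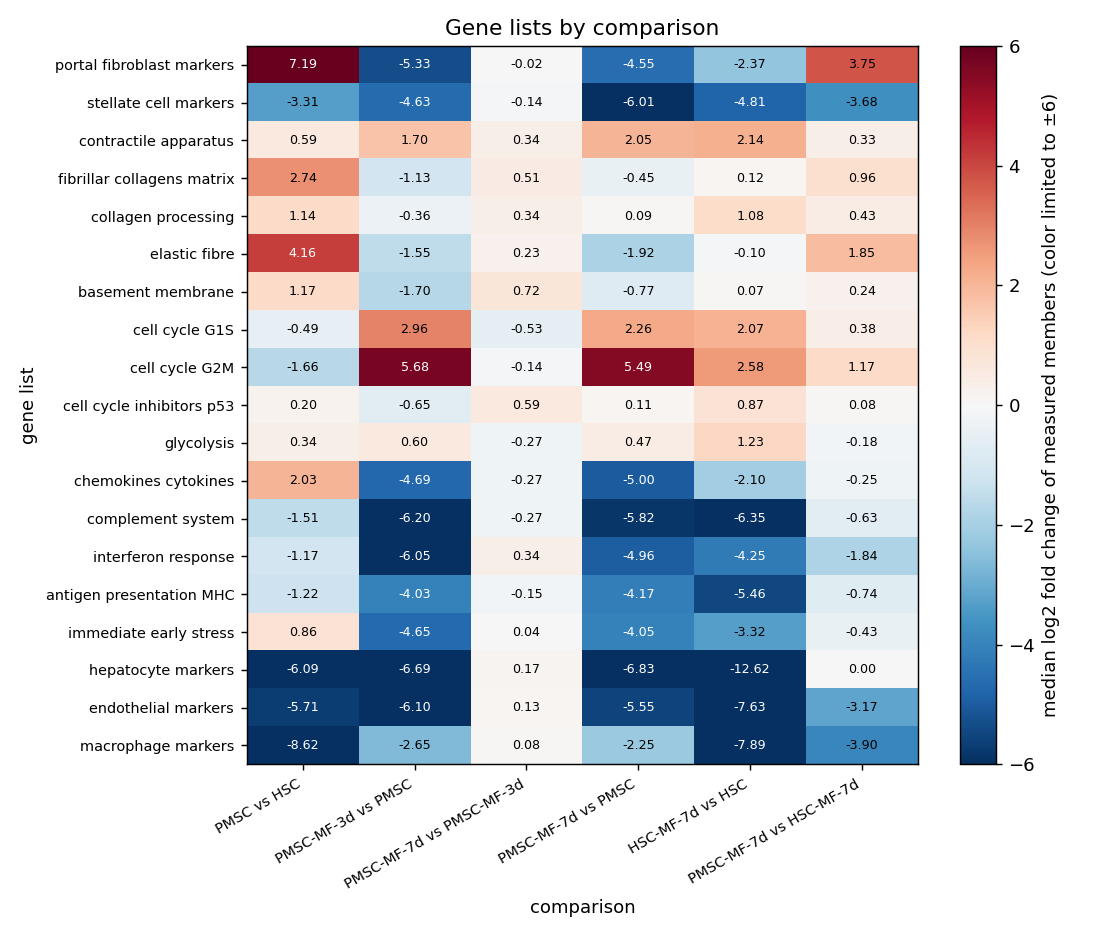
Median log2 fold change of the measured members of 19 gene lists in 6 comparisons, with members at 0 counts in a group set at their bound and the color limited to ±6. Contractile, G1/S and G2/M lists stand above 0 and interferon, antigen presentation and immediate-early lists below 0 in each comparison of cultured with fresh cells. Cell cycle inhibitors and p53 targets stand at -0.65 in PMSC-MF-3d against PMSC. The glycolysis list of PMSC against HSC has a median of 0.34 that falls to -0.00 with scaling by library totals.

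The matching comparison of HSC-MF-7d with fresh HSCs followed the stellate cells in culture. Acta2 rose from 8.46 ± 2.87 to 3218 ± 372 CPM (log2 fold change 8.57 ± 0.26, edgeR adjusted p = 1.3e-15). Timp1, Lox and Col1a1 rose by 7.40 ± 0.38, 7.91 ± 0.40 and 3.26 ± 0.33 (adjusted p at or below 2.8e-08). Lrat fell from 1568 ± 73.1 to 0.64 ± 0.51 CPM (-11.25 ± 0.48, adjusted p = 1.1e-13) and Reln to 217 ± 9.35 CPM (-4.91 ± 0.32, adjusted p = 4.1e-11). In total 5315 genes rose and 5674 fell, and of the 26 panel genes 11 rose, 12 fell and 3 did not pass, among them Il6 at 15.02 ± 8.25 and 22.98 ± 5.52 CPM (log2 fold change 0.61 ± 0.30, adjusted p = 0.075). Il6 passed without HSC replicate 1 or without HSC-MF-7d replicate 1.

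Of the 6 genes furthest up, 5 had no count in fresh HSCs. The vesicle protein gene Syt13 was at least 3191-fold higher, the cornified envelope gene Lce1h at least 2320.0-fold, the nephronectin gene Npnt at least 2120.0-fold, the Wnt antagonist gene Dkk2 at least 2091-fold and the BMP antagonist gene Grem1 at least 1351-fold. The heparan sulfate sulfotransferase gene Hs6st2 was 16540.0-fold (95% counting interval 2968 to 653200.0) higher. Genes known from hepatocytes were among those furthest down and went with the hepatocyte markers of the fresh HSC libraries. They included the fibrinogen genes Fgg (at least 11830.0-fold lower) and Fga (50890.0-fold (95% counting interval 9133 to 2010000.0)), Serpina1b (at least 6295-fold) and the serum amyloid genes Saa2 (at least 5833-fold) and Saa1 (at least 5753-fold). Over the 4 fresh HSC libraries Fgg averaged 493 ± 541 CPM and Saa1 239.6 ± 430.4 CPM, replicate 2 holding the most of both. Without that library the bounds fell to 5600.0-fold for Fgg, 473-fold for Saa2 and 598-fold for Saa1, and the fitted log2 fold change of Fga moved from -15.11 to -14.04.

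Stellate markers fell for 27 of 28 members (camera adjusted p = 7.3e-13), with Colec10 at -11.74 ± 0.42 and the metalloreductase gene Steap4 at -10.51 ± 0.64. Contractile genes rose for 20 of 22 and fell for 1 (camera adjusted p = 1.5e-18), with Cnn1 at 10.70 ± 0.39 and Tagln at 4.47 ± 0.25. G2/M genes rose for 27 of 30 (camera adjusted p = 1.2e-12; median 2.58), with Mki67 going from 27.9 ± 6.90 to 122 ± 10.9 CPM, and G1/S genes rose for 26 of 30 and fell for 1 (camera adjusted p = 4.5e-12). Collagen processing genes rose for 16 of 23 and fell for 4 (camera adjusted p = 3.0e-04, adjusted p = 0.20 with an estimated correlation; adjusted over the list alone 17 higher and 4 lower), with Loxl2 at 3.16 ± 0.18. Matrix proteases and their inhibitors rose for 12 of 22 and fell for 5 (camera adjusted p = 0.013, adjusted p = 0.14 with an estimated correlation), with Mmp10 at 13.13 ± 0.79 and Mmp13 at 7.40 ± 0.61. Targets of the mechanosensitive factors YAP and TEAD rose for 14 of 22 and fell for 7 (camera adjusted p = 3.8e-04, adjusted p = 0.14 with an estimated correlation), with Ankrd1 at 8.97 ± 0.54 and Ctgf at 4.21 ± 0.24. Glycolysis genes rose for 17 of 20 and fell for 2 (camera adjusted p = 8.4e-07), with Pgk1 at 2.54 ± 0.095. Vegfa, an angiogenic growth factor gene, rose by 2.71 ± 0.16.

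Interferon response genes fell for all 24 of 24 members (camera adjusted p = 3.3e-13), antigen presentation genes for all 16 of 16 (camera adjusted p = 1.4e-16) and complement genes for all 19 of 19 (camera adjusted p = 4.7e-09). Immediate-early and stress genes fell for 23 of 27 and rose for 1 (camera adjusted p = 4.6e-11, adjusted p = 0.12 with an estimated correlation), with Fos at -7.25 ± 0.47. Markers of other cell types fell with these groups. Hepatocyte markers fell for 22 of 23 (camera adjusted p = 6.3e-05, adjusted p = 0.47 with an estimated correlation), endothelial markers for all 20 of 20 (camera adjusted p = 3.4e-10, adjusted p = 0.14 with an estimated correlation) and macrophage markers for all 19 of 19 (camera adjusted p = 5.6e-07, adjusted p = 0.19 with an estimated correlation). Stab2 went from 1425 ± 126 to 1.01 ± 0.37 CPM and the Kupffer cell gene Cd5l from 1333 ± 752 to 1.03 ± 0.85 CPM. Without HSC libraries 1 and 2, which held the most hepatocyte transcripts, 5218 genes rose and 5356 fell, a setting chosen after the data were seen. Without HSC replicate 2 the log2 fold change of Cnn1 was 12.32 and that of Mmp10 14.78.

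The myofibroblasts of either origin were compared on day 7 by the sample titles. Thy1 averaged 495 ± 104 CPM in PMSC-MF-7d and 4.16 ± 2.84 in HSC-MF-7d (log2 fold change 6.90 ± 0.43, edgeR adjusted p = 2.2e-10), and Slit2 151 ± 91.5 and 2.65 ± 0.71 CPM (5.85 ± 0.42, adjusted p = 1.4e-09). Reln averaged 217 ± 9.35 CPM in HSC-MF-7d and 0.84 ± 0.45 in PMSC-MF-7d (-8.02 ± 0.40, adjusted p = 1.2e-11). Mki67 was higher in PMSC-MF-7d by 1.10 ± 0.22, Acta2 by 0.91 ± 0.19 and Col1a1 by 2.10 ± 0.31 (adjusted p at or below 5.0e-04). Across all genes 3532 were higher in PMSC-MF-7d and 3409 lower, and of the 26 panel genes 14 were higher and 5 lower.

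The genes furthest up in PMSC-MF-7d were the matrix Gla protein gene Mgp (8.09 ± 0.86), Vit (7.85 ± 0.46), Igfbp6 (7.21 ± 0.51), Col2a1 (7.17 ± 0.87), the fibromodulin gene Fmod (6.98 ± 0.67) and Thy1. Those furthest down were Psg22 (6400.0-fold (95% counting interval 2189 to 31040.0) lower), the BMP ligand genes Bmp10 (-11.66 ± 0.43) and Bmp5 (-8.60 ± 0.45), the carotene-cleaving enzyme gene Bco1 (-10.82 ± 0.34), Hcls1 (-9.64 ± 0.47) and the receptor gene P2ry14 (-9.04 ± 0.56). All 12 had an adjusted p at or below 3.8e-06.

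Portal fibroblast markers were higher in PMSC-MF-7d for 20 of 27 members and lower for 1 (camera adjusted p = 1.4e-10, adjusted p = 0.14 with an estimated correlation; adjusted over the list alone 21 higher and 2 lower), with Col15a1 at 6.87 ± 0.60. Stellate markers were lower for 23 of 28 and higher for 1 (camera adjusted p = 9.0e-23; adjusted over the list alone 2 higher and 23 lower), with Rgs5 at -7.46 ± 0.34 and Des at -3.02 ± 0.20. G2/M genes were higher for 29 of 30 (camera adjusted p = 2.2e-12, adjusted p = 0.11 with an estimated correlation; median 1.17), with Plk1 at 1.57 ± 0.21, Kif2c at 1.64 ± 0.18 and Ccnb1 at 1.37 ± 0.23. Elastic fibre genes were higher for 17 of 18 and lower for 1 (camera adjusted p = 7.2e-09, adjusted p = 0.14 with an estimated correlation), with Eln at 104 ± 76.97 and 0.93 ± 1.28 CPM. Fibrillar collagens and related matrix were higher for 14 of 24 and lower for 5 (camera adjusted p = 0.013, adjusted p = 0.62 with an estimated correlation), with Col6a3 at 3.70 ± 0.23 and tenascin-C (Tnc) at -4.67 ± 0.27. Contractile genes were higher for 12 of 22 and lower for 2 (camera adjusted p = 0.014, adjusted p = 0.58 with an estimated correlation; adjusted over the list alone 12 higher and 3 lower), with Actg2 at 2.42 ± 0.23. The matrix protease list was not called (camera adjusted p = 0.91), although Mmp13 (-6.74 ± 0.58) and Mmp3 (-6.43 ± 0.44) were lower. Interferon response genes were lower for 12 of 24 (camera adjusted p = 8.0e-06, adjusted p = 0.42 with an estimated correlation; adjusted over the list alone 15 lower). Antigen presentation genes were lower for 8 of 16 and higher for 1 (camera adjusted p = 1.2e-04, adjusted p = 0.40 with an estimated correlation; adjusted over the list alone 1 higher and 10 lower). Macrophage markers were lower for 14 of 19 (camera adjusted p = 1.9e-04, adjusted p = 0.52 with an estimated correlation), with the lysozyme gene Lyz2 at 3.91 ± 0.60 and 26.4 ± 5.97 CPM. Endothelial markers were lower for 15 of 20 (camera adjusted p = 8.4e-06, adjusted p = 0.52 with an estimated correlation; adjusted over the list alone 16 lower). The log2 fold change was -14.76 for Bmp10 without PMSC-MF-7d replicate 2, and 10.47 for Mgp, 9.41 for Igfbp6 and 8.498 for Eln without HSC-MF-7d replicate 1.

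The change of PMSCs in culture was then set against that of HSCs, gene by gene, as the difference between the log2 fold changes of PMSC-MF-7d against PMSC and of HSC-MF-7d against HSC. Acta2 rose by 4.996 in PMSC cultures and 8.57 in HSC cultures, a difference of -3.57 ± 0.28 (edgeR adjusted p = 2.1e-09), from fresh levels that differed as given above. Vegfa changed by -1.32 and 2.71 (difference -4.03 ± 0.22). Il6 changed by -6.52 in PMSC cultures against 0.61, not past the test, in HSC cultures (difference -7.13 ± 0.45; adjusted p at or below 1.3e-10). Ccnb1 rose by 7.49 and 3.09 (difference 4.39 ± 0.49, adjusted p = 3.1e-07; 5.58 without PMSC replicate 2). The culture change differed for 8943 of 14751 genes, and of the 26 panel genes 4 had a higher and 16 a lower change in PMSCs.

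G2/M genes rose more in PMSC cultures for all 30 of 30 members (camera adjusted p = 5.6e-17), with Cenpf at 5.71 ± 0.41 and Kif2c at 6.63 ± 0.47. Much of this lay in the fresh cells, where the list was lower in PMSCs (median log2 fold change -1.66) at low levels. Between the myofibroblasts the median was 1.17. The fresh HSC libraries also held markers of other cell types, and whether their G2/M transcripts came from stellate cells was not tested. Matrix proteases and their inhibitors had a lower change in PMSCs for 18 of 22 and a higher change for 1 (camera adjusted p = 2.1e-07; adjusted over the list alone 1 higher and 19 lower), with Mmp3 changing by -8.72 in PMSC and 8.30 in HSC cultures (difference -17.02 ± 0.70). Fibrillar collagens and related matrix had a lower change in PMSCs for 16 of 24 and a higher change for 4 (camera adjusted p = 1.4e-05, adjusted p = 0.21 with an estimated correlation), with Tnc at -7.43 ± 0.36 and Col12a1 at -6.91 ± 0.61. Collagen processing genes had a lower change for 17 of 23 and a higher change for 2 (camera adjusted p = 3.6e-04, adjusted p = 0.21 with an estimated correlation), with Lox at -5.74 ± 0.46. Portal fibroblast markers had a lower change for 16 of 27 and a higher change for 1 (camera adjusted p = 7.7e-05, adjusted p = 0.21 with an estimated correlation), with Fbln1 at -9.67 ± 0.22. In fresh PMSCs against HSCs the list medians were 1.92 for proteases, 2.74 for fibrillar collagens, 1.14 for collagen processing and 7.19 for portal markers. Between the myofibroblasts they were 0.38, 0.96, 0.43 and 3.75 in the same order on the log2 scale. The lower change of these lists thus started from higher fresh levels and did not leave a lower median in PMSC-MF-7d. Angiogenic factors had a lower change for 13 of 25 and a higher change for 3 (camera adjusted p = 5.2e-05), with the placental growth factor gene Pgf at -11.06 ± 0.67. Glycolysis genes had a lower change for 12 of 20 and a higher change for 4 (camera adjusted p = 0.0019, adjusted p = 0.10 with an estimated correlation), with the hexokinase gene Hk2 at -6.20 ± 0.32 and the lactate transporter gene Slc16a3 at -4.997 ± 0.30. In PMSC cultures alone the list went both ways, with 11 members higher and 6 lower, and was not called (camera adjusted p = 0.13). Clec4f and other macrophage markers fell in HSC cultures from the levels given for fresh HSCs, and hepatocyte and endothelial markers with them. Without PMSC replicate 2 the difference was 6.81 for Cenpf, and it was -8.40 for Col12a1 without HSC replicate 2.

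Of the genes that changed in both cultures, 3396 rose in both and 3553 fell in both, where independent lists would share 2022.4 and 2210.2. A further 796 rose in PMSC and fell in HSC cultures while 929 did the reverse. Across genes, which are not independent replicates, the culture changes had a Pearson r of 0.585 and a Spearman rho of 0.543, from comparisons with no library in common. Of the 10872 genes that differed between fresh PMSCs and HSCs, 30.99% also differed in the same direction between PMSC-MF-7d and HSC-MF-7d, 17.81% differed in the opposite direction and 51.2% did not pass the test there. The 4959 genes higher in fresh PMSCs held 1696 that were also higher in PMSC-MF-7d, where independent lists would share 1187.4. The 5913 lower ones held 1673, where independent lists would share 1366.5. The SD over genes of the log2 fold changes was 2.82 between the fresh cells and 1.52 between the myofibroblasts. The correlation moved from 0.585 to 0.425 without 1652 genes that fell more than 10-fold in HSC cultures, a setting chosen after the data were seen that selects genes on the HSC change itself. The share of called genes with a higher change in PMSCs went from 51.8% with trimmed means to 66.0% with library totals, 48.2% with DESeq2 size factors and 68.0% with limma on log2(TPM + 1).

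**Figure D4:**
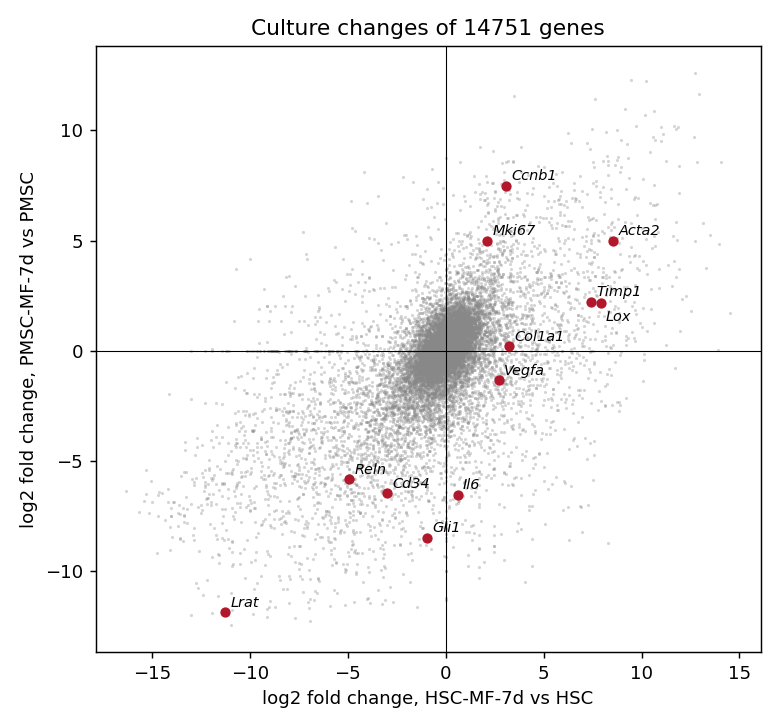
Log2 fold change of each of 14751 genes in PMSC cultures (vertical axis) against that in HSC cultures (horizontal axis), with 12 genes named. Acta2, Timp1 and Lox lie to the right and Mki67 and Ccnb1 to the upper right of 0 on both axes, Il6 and Vegfa lie below 0 for PMSCs, and r across genes is 0.585.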

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

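The tests of hepatocyte genes and of Lrat, and the splits of the libraries for PMSC against HSC and for the difference of the culture changes, were chosen only after the result was seen; the tests of the day of culture and of depth, and the other splits, were written before.

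The 26 panel genes and 3 measures of each library (total count, genes with a count and the share of the top 10 genes) made 145 sets of 4 libraries over the 5 groups. In 9 of these, each a gene's CPM, a library stood apart from the other 3, where chance gives about 5%. In fresh HSC these were the highest libraries of Slit2 (0.06), Col1a1 (516.3) and Timp1 (5.96). In fresh PMSC they were the highest of Col3a1 (14090.0), Lox (1068.0) and Mki67 (15.41). In PMSC-MF-3d it was the highest of Lrat (0.04), and in HSC-MF-7d the highest of Eln (2.84) and the lowest of Ccnb1 (23.05). Slit2 and Lrat each held a single count over the 4 libraries, which must stand apart from 0 in the others, so they say nothing against that chance share.

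The culture change differed between PMSC and HSC by an edgeR test of the difference itself for 20 of the 26 panel genes. Among the markers of fresh cells the difference was -3.49 for Cd34, 5.26 for Ly6a, -7.53 for Gli1, -1.09 for Pdgfra, -2.61 for Des and -2.05 for Ngfr on the log2 scale. For Slit2 it was -6.63, a fitted value that is no bound, since fresh HSC held a single count. Among the genes of myofibroblasts it was -3.57 for Acta2, -1.35 for Tagln, -3.04 for Col1a1, -1.91 for Col3a1, -5.18 for Timp1 and -5.74 for Lox. Cell cycle genes differed by 2.86 for Mki67, 3.48 for Top2a and 4.395 for Ccnb1. The signalling genes differed by -0.64 for Jag1, -7.13 for Il6, -3.29 for Ccl2 and -4.03 for Vegfa. That of Ngfr turned to 0.056 with limma on log2(TPM + 1). That of Jag1 was no longer called without HSC replicate 1, HSC replicate 2, HSC-MF-7d replicate 1 or PMSC-MF-7d replicate 2, left out singly. The difference of Gli1 was -9.05 and that of Slit2 -8.40 without HSC replicate 3, and that of Ccnb1 5.585 without PMSC replicate 2.

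Hepatocyte, endothelial and macrophage genes stood higher in the fresh HSC libraries than in fresh PMSC and in HSC-MF-7d. For each of the 3 marker lists at least 95% of the measured members did so in each comparison taken singly. RNA of other liver cells in a mixed preparation, a candidate explanation, would give this. The share restates the pattern that prompted the test, so it does not single out that explanation. The most abundant genes of these lists, such as Alb, Stab2 and Clec4f, stood in fresh HSC at 6463 ± 4096, 1425 ± 126 and 1319.5 ± 761 CPM. The median of hepatocyte genes varied over the 4 HSC libraries by 2.73 on the log2 scale against 0.49 for stellate genes, a difference of 2.24, which argues against the hepatocyte genes being expressed by the stellate cells at a level shared by the preparations. That of macrophage genes varied by 1.79 and that of endothelial genes by 0.228, so the argument does not reach them; expression that differs between preparations or is lost in culture stays open, only Robo4 of these lists is on another list, and the labels give no sort or gate.

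Lrat averaged 10.3% of its HSC level in fresh PMSC, and it might come from stellate cells in those libraries. Of the 28 stellate markers with at least 100 CPM in HSC, Lrat included, 9 had their highest share of the HSC level over the PMSC libraries below the lowest of Lrat, 5.67%, which argues against stellate RNA as the whole source of Lrat. Among these were Reln at 0.72%, Colec10 at 0.38%, Fcna at 0.058% and Rgs5 at 1.29%, while Ecm1 at 15.8% and Cygb at 370% stood above Lrat. A bound on the mean ± 2 SD was used before this one, and could decide nothing because that of Lrat lay below 0. Low expression in the portal cells themselves stays open.

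G2/M genes were higher in PMSC-MF-7d than in HSC-MF-7d, and the day of culture or the depth of the libraries could give this. The series description puts the HSC-MF libraries on day 3, and 28 of the 30 G2/M genes were called higher in PMSC-MF-3d too. The G2/M list hardly moved from PMSC-MF-3d to PMSC-MF-7d (median log2 fold change -0.14), so this outcome was close to settled beforehand. No library shows the time course of the stellate cells, so the test cannot decide whether their day of culture matters. With PMSC-MF-7d thinned to the lowest total of the HSC-MF libraries 29 were called higher, as many as without. This argues against depth as the source of the number of calls. A difference of growth between the cell types, named by the design, stays open and untested, as do the day of culture and culture conditions.

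In each of the 6 comparisons of groups only 1 of 35 splits of the 8 libraries, the real one, gave as many edgeR calls. These were fits of those libraries alone. Every other split mixes both groups, which widens the spread within its parts, so few calls were possible there. The splits therefore speak only against a random labelling of these libraries. They cannot exclude chance differences between animals, preparations or cultures, since the origin of the libraries is not given. The real splits called 9159 genes for PMSC against HSC, 10581 for PMSC-MF-3d against PMSC and 6453 for PMSC-MF-7d against PMSC-MF-3d. They called 10056 for PMSC-MF-7d against PMSC, 10574 for HSC-MF-7d against HSC and 7873 for PMSC-MF-7d against HSC-MF-7d. No other split called any gene in edgeR, and the most at an unadjusted p under 0.05 were 744, 564, 1646, 769, 365 and 1228 in the same order. For the difference of the culture changes the real split called 8481 genes, 1 of 100 splits giving as many. The highest of the other splits called 7540, 6698, 6641, 6630, 6572, 923 and 808 genes, while their median was 0. In these splits the fresh and the cultured libraries were relabelled separately. A split can therefore keep the real division of the fresh or of the cultured libraries, and with it a real difference. Which splits did so was not recorded, so the high counts do not show what a wrong labelling of both would call. The number of calls alone does not exclude chance there.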

How the results depend on the processing

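The alternatives without HSC libraries 1 and 2, without PMSC-MF-7d libraries 1 and 2 and without genes that fell more than 10-fold in HSC cultures, and camera with both the replicate block and an estimated correlation, were chosen after the data were seen, and the other alternatives before.

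Of 479 values of the 15 counts, shares and correlations, 463 stayed within the limits set for the same result and 16 moved. A count was the same within a ratio of 1.5, and a share or correlation within its jackknife standard error. Of the 463, 299 came from leaving out a single library. The limits on counts and on the share kept are wide. Library totals kept all 15, although 9722 of the 10872 calls of PMSC against HSC were shared in direction. Against a fold change of 1.5 (glmTreat), 3445 genes rose in HSC-MF-7d, 1383 were higher and 1481 lower in PMSC-MF-7d than in HSC-MF-7d, and 770 rose and 494 fell from PMSC-MF-3d to PMSC-MF-7d. There 3807 genes were lower in PMSC than in HSC, the culture change differed for 5852 genes and the share of fresh differences kept was 19.11%, each from a stricter test. The share was 39.61% with only the libraries of the groups compared. There the spread, the filter and the scaling came from those libraries alone. Calls fell from 10872 to 9159 between the fresh cells and rose from 6941 to 7873 between the myofibroblasts, and the cause was not tested.

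The correlation of the culture changes, 0.585, was 0.509 with DESeq2, 0.497 with no filter, 0.675 with the 10 CPM filter and 0.652 with only the libraries of the groups compared; the cause was not tested. It was 0.547 without HSC libraries 1 and 2, 0.535 without PMSC replicate 2 and 0.425 without the genes that fell more than 10-fold, which selects genes on the HSC change. No correlation was made under glmTreat. Over the 20 libraries left out singly it ranged from 0.535 to 0.579, each under the value with all 20, and the share kept from 27.78% to 31.68%. The jackknife standard error was 5.94 for the share in percentage points and 0.036 for the correlation. It treated the 20 libraries of 5 groups as a single sample, so it is only a rough limit.

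Leaving out each library gave 4891 to 5212 genes higher and 5489 to 6042 lower in PMSC than in HSC. It gave 5245 to 5645 higher and 5823 to 6107 lower in PMSC-MF-3d, 2301 to 2909 higher and 2148 to 2978 lower from day 3 to day 7, and 5163 to 5809 higher and 5506 to 5859 lower in PMSC-MF-7d than in PMSC. In HSC-MF-7d it gave 5231 to 5559 higher and 5495 to 5853 lower than in HSC. Between the myofibroblasts it gave 3161 to 3717 higher and 3047 to 3715 lower, and the culture change differed for 8595 to 8983 genes.

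Without HSC libraries 1 and 2, 4826 genes were higher and 5557 lower in PMSC than in HSC, and the share kept was 31.78%. Without PMSC-MF-7d libraries 1 and 2, 2105 genes rose and 1929 fell from day 3 to day 7, the share kept was 25.53% and the correlation 0.556.

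The 1126 results of named genes gave 35651 values under the alternatives, of which 35246 kept their direction and side of the threshold, 362 lost the call, 39 gained it and 4 reversed. Apart from the panel, these genes were picked as called genes with the largest changes, so keeping the call says little about other genes. The reversed ones were in the difference of the culture changes under limma on log2(TPM + 1), with Foxf2 at 0.44, Lrat at 3.47, Ngfr at 0.056 and Reln at 2.08, and the cause was not tested. DESeq2 gave no adjusted p for 3. The 280 list results gave 1120 values, of which 813 kept their side of the threshold, 219 lost the call and 88 gained it, 84 of these with fry. Of the losses 208 came with an estimated correlation, 93 without and 115 with the replicate block.

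Replicate numbers are shared between groups, and the libraries were not treated as paired. Same-numbered libraries correlated best with their own number for 3 of 4 from PMSC-MF-3d to PMSC-MF-7d, with correlations of deviations from 0.002 to 0.122, and for up to 2 of 4 elsewhere. The highest such correlation, 0.145, was between replicate 2 of PMSC and of HSC, where 1 of 4 did so. With the replicate block 4896 genes were higher and 5876 lower in PMSC than in HSC, and each of the 15 counts, shares and correlations kept within its limits. Of the 124 list calls of camera, 113 held with the block, 31 with an estimated correlation and 9 with both, 7 of which are among the 31; the cause was not tested. The 9 were angiogenic factors, matrix proteases and macrophage markers in PMSC against HSC, and antigen presentation, G1/S, complement, contractile and glycolysis genes and macrophage markers in HSC-MF-7d against HSC. No other list call was kept with both. Lost with the block alone were BMP, glycolysis and protease genes in PMSC-MF-3d against PMSC, BMP and lipid storage genes in PMSC-MF-7d against PMSC, and chemokines in HSC-MF-7d against HSC. Fibrillar collagens and vascular smooth muscle markers between the myofibroblasts, and G1/S, p53 and endothelial genes in the difference of the culture changes, were also lost.

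Depth limits the low end. Genes at 0 counts in a group can lie up to the floor given in the methods. Differences under about 2-fold were often missed in simulated data, where far fewer genes changed than were called here.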

Other observations

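The cartilage, bone and tendon lists were chosen after other results had been seen, and the other lists before. Pathway genes of the mesenchyme differed between fresh PMSCs and HSCs. Wnt pathway genes were higher in PMSCs for 20 of 30 and lower for 5 (camera adjusted p = 0.0019, adjusted p = 0.17 with an estimated correlation), and hedgehog pathway genes for 10 of 15 and lower for 3 (camera adjusted p = 0.0019, adjusted p = 0.17 with an estimated correlation). TGF-beta pathway genes were higher for 17 of 24 and lower for 3 (camera adjusted p = 4.4e-04, adjusted p = 0.064 with an estimated correlation; adjusted over the list alone 17 higher and 5 lower), angiogenic factors for 18 of 25 and lower for 5 (camera adjusted p = 2.2e-05), and contractile genes for 12 of 22 and lower for 5 (camera adjusted p = 0.0057, adjusted p = 0.36 with an estimated correlation).

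In PMSC-MF-7d against PMSC, hedgehog genes fell for 12 of 15 and rose for 2 (camera adjusted p = 0.0015, adjusted p = 0.15 with an estimated correlation), Notch genes fell for 12 of 16 and rose for 2 (camera adjusted p = 0.012, adjusted p = 0.23 with an estimated correlation) and BMP genes fell for 15 of 25 and rose for 8 (camera adjusted p = 0.044, adjusted p = 0.23 with an estimated correlation). Angiogenic factors fell for 16 of 25 and rose for 3 (camera adjusted p = 0.0089, adjusted p = 0.11 with an estimated correlation), and retinoid handling genes fell for 15 of 20 and rose for 3 (camera adjusted p = 0.0071, adjusted p = 0.18 with an estimated correlation).

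In HSC cultures retinoid handling genes fell for 12 of 20 and rose for 5 (camera adjusted p = 0.018, adjusted p = 0.21 with an estimated correlation), lipid storage genes fell for 10 of 16 and rose for 1 (camera adjusted p = 0.013, adjusted p = 0.23 with an estimated correlation) and Notch genes fell for 13 of 16 and rose for 3 (camera adjusted p = 0.0076, adjusted p = 0.19 with an estimated correlation). Cell cycle inhibitors and p53 targets rose for 11 of 18 and fell for 7 (camera adjusted p = 0.0099).

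Between the myofibroblasts, vascular smooth muscle and pericyte markers were higher in PMSC-MF-7d for 7 of 14 and lower for 6 (camera adjusted p = 0.025, adjusted p = 0.40 with an estimated correlation), with a positive median of 0.38 while camera's direction was down.

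TGF-beta genes had a lower change in PMSC than in HSC cultures for 16 of 24 and a higher change for 4 (camera adjusted p = 5.2e-05), and hedgehog genes a lower change for 11 of 15 (camera adjusted p = 0.0010, adjusted p = 0.16 with an estimated correlation). Wnt genes had a lower change for 19 of 30 and a higher change for 3 (camera adjusted p = 0.0015, adjusted p = 0.16 with an estimated correlation), chemokine and cytokine genes for 18 of 28 and for 2 (camera adjusted p = 5.0e-04, adjusted p = 0.094 with an estimated correlation) and immediate-early and stress genes for 16 of 27 and for 2 (camera adjusted p = 1.6e-04, adjusted p = 0.35 with an estimated correlation).

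Of the 40 lists, 9 were not called by camera in any comparison, the lowest adjusted p being 0.093 for mesenchymal stem cell markers, 0.13 for axon guidance genes, 0.52 for protein folding genes, 0.31 for cholesterol synthesis genes and 0.51 for cholangiocyte markers. It was 0.36 for lymphocyte and granulocyte markers, 0.35 for mesothelial markers, 0.059 for Schwann and neural markers and 0.29 for erythroid markers. Stellate and portal marker lists share genes with other lists.

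Genes of other cell types were traced through the cultures. Of the hepatocyte markers, 22 of 23 reached at least 1 CPM in fresh PMSC and 23 in HSC, but 1 in PMSC-MF-3d, 2 in PMSC-MF-7d and 3 in HSC-MF-7d. Of the endothelial markers 20 of 20 did in fresh PMSC and in HSC, 4 in each PMSC culture and 15 in HSC-MF-7d. Of the macrophage markers 5 of 19 did in fresh PMSC, 19 in HSC, 3 in each PMSC culture and 11 in HSC-MF-7d.

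The rise of Col2a1 from day 3 to day 7 of the PMSC cultures raised the hypothesis that a cartilage, bone or tendon programme was rising, and the 3 list tests were written before their results were seen. The lists left out genes whose values had been seen. The tests gave no support for a rise. By edgeR, 4 of 17 cartilage genes rose and 2 fell, 5 of 10 bone genes fell and 1 rose, and 5 of 11 tendon genes fell and 1 rose. The p of camera in limma was 0.39 for the cartilage list and 0.13 for the tendon list. It was 0.0055 for the bone list (adjusted p = 0.017), which went down, a call not kept with an estimated correlation (adjusted p = 0.073).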
